A study of Homo sapiens with 52 samples.

How the data were processed

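Polyadenylated RNA from 26 human cancer cell lines was sequenced, 1 library with the shLuc hairpin and 1 with the shKdm5b hairpin per line. Per the labels' protocols, RNA was extracted with an RNeasy kit (Qiagen) and libraries were made with the NEBNext Ultra II RNA kit for Illumina. Per the submitters' processing notes, Bowtie2 (version not given) and the genome build hg19 were used. The counting tool and whether it used strand are not given in the sources used here. Each deposited table lists 59443 RefSeq transcripts with a read count per transcript, which the authors deposited without normalization, and the RPKM value the authors computed from it (reads scaled to transcript length and library size). The library totals behind the deposited RPKM values, recovered from count, length and RPKM, were 28564584 to 62789349. An entry with no transcript name, found in 10 of the tables with 0 counts, was left out. Symbols of 106 transcripts that had been turned into dates were looked up by accession, and 1 had no match.

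Each of 27309 gene symbols was represented by 1 fixed transcript, the one with most counts over all libraries, since the transcripts of a gene share reads. A value is therefore that of 1 isoform for the 11926 genes with several. The resulting gene-level counts were 18309400 to 40419133 per library, with a median of 23428446. At that depth the error of a gene's change comes mainly from the spread between lines, except for genes of few counts. For some of these, counts or RPKM values are given. Counting precision covers reads, not molecules, since no molecular identifiers are recorded. Genes with an RPKM of at least 1 in at least 4 of the 52 libraries, 16940 in all, were tested.

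The design assumed RPKM alone and named a count test in case the tables held counts, which they did. The main test was the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on counts with TMM scaling and the cell line as a block, with Benjamini-Hochberg adjustment at 0.05. The pairing comes from the labels, which name the cell line of each library. All 52 libraries correlated best with the other library of their own line (0.938 to 0.990, highest correlation between lines 0.901). One fit gave a single knockdown effect, a second gave 1 effect per panel with a shared spread, and an F test compared the panels. A per-line log2 change is the difference in log2 CPM (counts scaled to library size) with a prior count of 2, or, for markers, counts of changed genes and similarity, in log2(RPKM + 1), which understates changes of low genes.

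Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, for lists with at least 5 tested members. Values over lines were tested with two-sided sign-flip or permutation tests (100000 resamples). Similarity was tested with 10000 random swaps, and with fewer in subsets of lines. Sign-flip tests were exact for fewer than 10 lines. Genes are named by a rule: KDM5B and the H3K4 list; the 12 largest rises and 12 largest falls among genes past the test that moved that way in at least 18 lines; the members of each list with the smallest p; the 3 largest rises and falls per panel; the 6 genes with the smallest p between panels; and, in each line, the own-list members with the largest change. A few examples of each are printed, and genes of the Y chromosome and XIST are not named. The grouping, tests, gene lists, naming rule and the alternatives listed next were fixed before the data were examined. These alternatives were no pairing, other scalings, filters, pseudocounts and tools (limma, DESeq2 1.42.0), single flow cells, and leaving out each line or panel in turn.

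The search for 7-base words in 3' UTRs was added after the changed genes were seen. Annotated 3' UTRs of at least 50 bases were taken from GENCODE v29 (GRCh38) as sequence only, with no coordinates, for 14119 genes. Of the tested genes 96.2% matched by symbol, some through older symbols. Each word present in at least 30 genes was scored in a regression on the test statistic, adjusted for 3' UTR length, its GC share and expression. Of a gene's 3' UTR, only the annotated sequence was searched, and the isoform in the cells can differ. The adjustment for GC share, an equal weight for each line and effects from the regression were added after the first version of the word tests had been seen, whose values are given among the other observations. The lines were also divided into 2 sets of 13 by alternate position, and the signs of whole lines were flipped 1000 times. Sequencing flow cells, used as batches, are known only from the deposited data's naming: hky73bbxx held both libraries of 17 lines, H5TJWDMXX of 5 and HFCGKDMXX of 3, while those of HL-60 were on different flow cells.

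The steps were tested on simulated data with known changes. Over 16940 genes the fit over all lines recovered 60% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1, with 1.86% false calls among all calls. The ME panel effect was recovered for 58% of genes changed by 1 and 96% of those changed by 2, with 4.35% false calls. The F test between panels recovered 28% and 91% of these sizes, with 3.25% false calls. The simulated counts were independent between genes and had the same spread in every line. Changes were planted only in genes with a mean RPKM of at least 1. The real lines differed in spread, with SDs of the log2 changes from 0.466 in NCI-H23 to 1.17 in A498. These rates therefore hold for the simulated setting and need not hold for the real panels. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.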

Results

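Polyadenylated RNA was sequenced from 26 established human cancer cell lines, each carrying in 1 library a short hairpin labelled shLuc, the control arm, and in the other a hairpin labelled shKdm5b, directed at the histone demethylase gene KDM5B. The 52 libraries thus formed 26 pairs. The panel codes that open the sample titles grouped the lines into BR (3 lines), CNS (3), LC (6), LE (3), ME (6), OV (3) and RE (2). Counts summed over genes ranged from 18309400 to 40419133 per library, with a median of 23799663 in the shKdm5b arm and 23307238 in the shLuc arm. The replicates of every test were cell lines, each with 1 library per arm, so a single line's change had no replicate of its own. No library without a hairpin was analysed here, so each change is a difference between the hairpins.

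KDM5B, which encodes a demethylase of methylated lysine 4 on histone H3 (H3K4), was lower in the shKdm5b library in 26 of 26 lines. Its level averaged 6.43 ± 4.16 RPKM (SD, n = 26) with shLuc and 1.41 ± 0.71 RPKM with shKdm5b. The log2 change was −2.05 (SE 0.16, adjusted p = 1.36e-09, edgeR quasi-likelihood test). The remaining level ran from 8.51% of the paired shLuc library in NCI-H522, a line of the LC panel, to 60.7% in the RE line A498, with a median of 24.4%. A two-sided sign-flip permutation test of the 26 differences gave p = 1e-05, the smallest that 100000 resamples can give. Within the sequencing flow cell hky73bbxx, which held both libraries of 17 lines, the log2 change was −2.06 (adjusted p = 1.01e-05). The flow cells H5TJWDMXX and HFCGKDMXX held 5 and 3 lines, and there the fits gave −2.29 and −1.88 but passed the test for no gene.

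**Figure D1:**
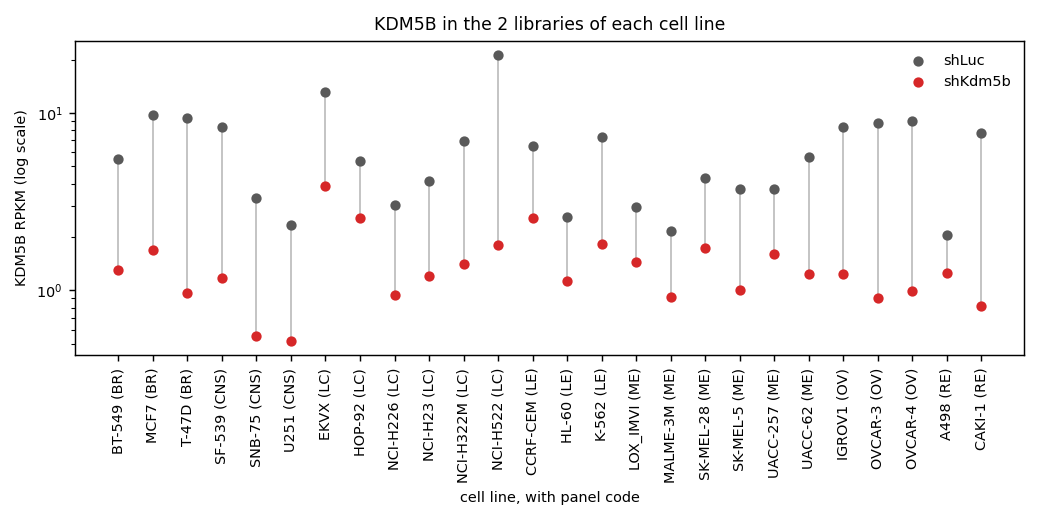
KDM5B RPKM (log axis) in the shLuc library (grey) and the shKdm5b library (red) of each of the 26 lines, with the panel code beside the line name and a bar joining each pair. The shKdm5b point lies below the shLuc point in 26 of 26 lines, and the pair of A498 lies closest, at 60.7% of shLuc.

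The other 19 tested genes of H3K4 enzymes and their partners, a list of 20, did not pass the test. Their log2 changes lay between −0.12 and 0.10. The related demethylase genes KDM5A and KDM5C had log2 changes of −0.06 (SE 0.06) and −0.07 (SE 0.06), and CXXC1, a subunit of H3K4 methyltransferase complexes, −0.12 (SE 0.08). Of the list, 9 members were positive and 11 negative, and as a set it did not differ from other genes (camera, adjusted p = 0.305). Adjusted over the list alone, KDM5B fell and no other member passed.

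The comparison of shKdm5b with shLuc over all lines asked which genes moved in common across the lines. HNRNPAB, which encodes an RNA-binding protein, rose by a log2 change of 1.23 (SE 0.12, adjusted p = 2.39e-07) and was higher in 26 of 26 lines, at 151 ± 65.4 RPKM against 67.8 ± 39.7 (SD, n = 26). MDH1, the cytosolic malate dehydrogenase, rose by 1.16 (SE 0.14, adjusted p = 9.57e-06), and MIGA1, a gene of mitochondrial fusion, by 1.07 (SE 0.11, adjusted p = 2.39e-07), both also in 26 of 26 lines. FTH1, the heavy chain of the iron store ferritin, rose by 1.04 (SE 0.18, adjusted p = 0.000899) in 22 lines, from 493 to 857 RPKM. Of the falls after KDM5B, the steepest was that of GUCY1B3, a subunit of soluble guanylate cyclase, which fell by 1.14 (SE 0.26, adjusted p = 0.0239) and was lower in 19 lines and higher in 3. C1orf109 fell by 0.82 (SE 0.08, adjusted p = 1.53e-07) in 25 lines.

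The other large rises included ALDH1A2, which makes retinoic acid, at a log2 change of 1.39 (20 lines higher, 4 lower, adjusted p = 0.000468), the growth factor receptor gene PDGFRB at 1.04 (21 lines) and the metalloprotease gene ADAM12 at 1.003 (19 lines). The calls of these 3 genes and of GUCY1B3 were lost by limma on log2(RPKM + 1), which gave 0.23 for ALDH1A2, 0.20 for PDGFRB, 0.37 for ADAM12 and −0.30 for GUCY1B3, and also with median-centred values and with array weights on that scale. ISOC1 rose by 1.12 in 25 lines, the long noncoding RNA BLACAT1 by 1.30 in 23, the pseudogene PPP1R2P3 by 1.09 in 23, TEX19 by 1.08 in 23 and PQLC3 by 1.03 in 22. Among the falls, FDX1L had −0.97 and was lower in 25 lines, SSH1, a cofilin phosphatase, −0.63 in 24, SSBP2, a single-stranded DNA binding protein, −0.73 in 22, SMCO4 −0.66 in 24 and CA11 −0.62 in 22. The noncoding LINC01963, LOC101927181, OTUD6B-AS1 and LOC101927204 fell by 0.74, 0.72, 0.70 and 0.64. OTUD6B-AS1 is antisense to OTUD6B, and whether the counting used strand is not given in the sources used here. FTH1 and PPP1R2P3 share sequence with near-identical copies, so their values are uncertain. The values of HNRNPAB and MDH1 belong to 1 isoform each. Some of the named genes lay low in both arms. Mean RPKM with shLuc and shKdm5b was 0.29 and 0.55 for TEX19, 0.62 and 1.11 for BLACAT1 and 0.82 and 0.59 for SSBP2. It was 1.31 and 0.92 for LOC101927204 and 1.54 and 0.62 for GUCY1B3.

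In all, 198 genes rose and 83 fell of 16940 tested (edgeR, adjusted p under 0.05), and 2246 had an unadjusted p under 0.05. The excess of rises depended on the method: limma on log2(RPKM + 1) called 135 higher and 128 lower, 142 and 134 with a pseudocount of 0.1, and 179 and 238 with array weights. The changed genes had a median absolute log2 change of 0.42, while the median log2 change of all genes was 0.00. Of the risen genes, 197 were higher in at least 18 lines, and of the fallen, 82 were lower in at least 18. Within flow cell hky73bbxx 109 genes changed (89 higher, 20 lower), while within H5TJWDMXX and HFCGKDMXX the edgeR test called 0 genes, with 731 and 728 at an unadjusted p under 0.05. Without the pairing of libraries by line, 5 genes changed, and DESeq2 called 615. Without the LC or ME panel the count was 103 or 124, without the RE panel 315 genes were higher and 183 lower, and without the line U251 the count was 183 and without A498 506.

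**Figure D2:**
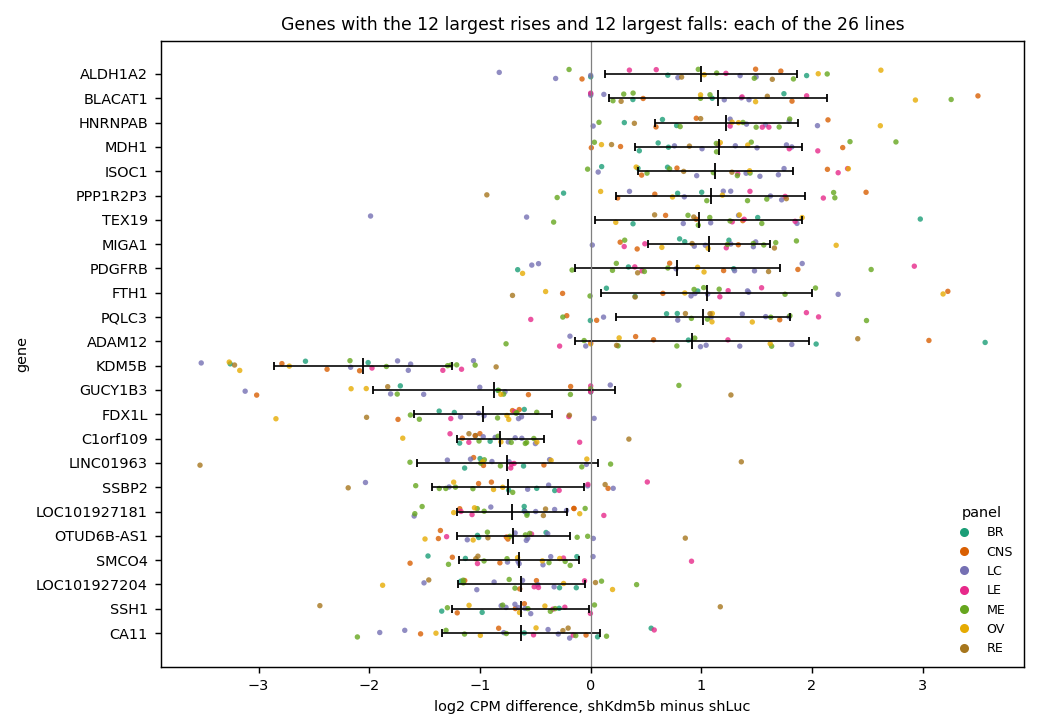
Difference in log2 CPM (counts scaled to library size) between the shKdm5b and the shLuc library in each of the 26 lines (points, coloured by panel) for the genes with the 12 largest rises and the 12 largest falls, with the mean (tick) and SD over lines (bar). For HNRNPAB, MDH1 and MIGA1 all 26 points lie above 0, and for KDM5B all 26 lie below 0.

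The risen genes shared a short sequence. This was looked for after the changed genes were seen. Of 183 risen genes with an annotated 3' UTR of at least 50 bases, 120 (65.6%) held the 7-base word GTACCAA in it, against 6.97% of all 14119 genes searched. HNRNPAB, MDH1, MIGA1, ISOC1, FTH1, ALDH1A2, PDGFRB, PQLC3 and ADAM12 carried it, TEX19 did not, and BLACAT1 and PPP1R2P3 were not searched. Genes with the 8-base form GTACCAAA had a median log2 change of 0.14 (SD 0.29, n = 396 genes), those with GTACCAA alone 0.09 (SD 0.25, n = 588), those with TACCAAA 0.02 (SD 0.21, n = 1495), those with the 6 bases TACCAA alone −0.01 (SD 0.20, n = 1545), and genes with none of these sites 0.00 (SD 0.22, n = 10095). Of the fallen genes, 14 of 68 (20.6%) held ATCGATA, against 1.24% of genes searched, among them GUCY1B3, C1orf109, SSBP2 and SMCO4. SSH1, which fell, held GTACCAA.

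Of 16374 words tested, GTACCAA had the strongest association with rises (t = 28.1) and ATCGATA with falls (t = −10.3). Genes with GTACCAA moved up relative to other genes in 26 of 26 lines, by a mean log2 effect of 0.15 ± 0.09 (SD, n = 26), and genes with ATCGATA moved down in 25 of 26, by −0.13 ± 0.08, with A498 at 0.03. In the first version of the word tests, without the GC share and with differences of means, these were 21 and 24 of 26 lines. When the direction of each line was flipped at random 1000 times, no word reached the association of GTACCAA (permutation p = 0.000999 over all words, the smallest possible). ATCGATA did not pass that test (p = 0.325 over all words). In the version adjusted for GC share, the effect of GTACCAA showed no relation to the KDM5B change over lines that passed a test. Pearson's r was 0.193 (permutation p = 0.346) and Spearman's rho 0.216 (p = 0.290). The first version gave r = 0.537 (permutation p = 0.0037), with a larger effect where KDM5B fell less. The effect of ATCGATA was more negative where KDM5B fell more, with r = 0.476 (permutation p = 0.0145, adjusted p = 0.0289) and rho = 0.510 (p = 0.00875, adjusted p = 0.0289). These p-values were adjusted over both coefficients of the 2 relations together. Without the 2 lines farthest from the median KDM5B change r was 0.312 for GTACCAA and 0.465 for ATCGATA, and within hky73bbxx −0.0675 (p = 0.80) and 0.634 (p = 0.00763). With genes holding either word set aside and the p-values adjusted again over the rest, 61 genes changed (32 higher, 29 lower). This count mixes the removal with the new adjustment. Of the called genes, 120 risen and 3 fallen held GTACCAA, and 1 risen and 14 fallen held ATCGATA.

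**Figure D3:**
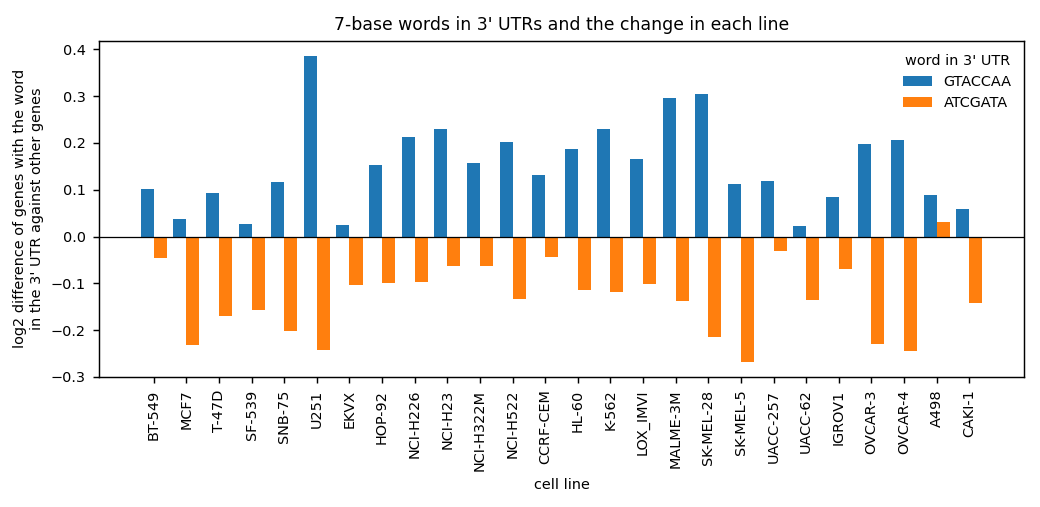
Log2 effect in each of the 26 lines of carrying GTACCAA (blue) or ATCGATA (orange) in the annotated 3' UTR, adjusted for 3' UTR length, its GC share and expression, as shKdm5b minus shLuc. The GTACCAA bars lie above 0 in 26 of 26 lines, between 0.02 and 0.39, and the ATCGATA bars below 0 in all but A498.

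Of 30 gene lists tested over all lines, 4 differed from other genes by camera with a preset correlation, and none of these 4 calls held with an estimated correlation (adjusted p = 0.435 for ribosome biogenesis and 0.725 for each of the other 3). Over lines, the median of the list was positive in 17 of 26 for ribosome biogenesis, 14 for G2 and M, 13 for cholesterol synthesis and 8 for p53 targets, and no list passed (sign-flip permutation p = 0.0529, 0.147, 0.221 and 0.0985), with G2 and M highest in OVCAR-4 (1.07) and CAKI-1 (0.88). Ribosome biogenesis genes were higher in 20 of 20 members (median log2 change 0.14, adjusted p = 2.80e-06). NPM1, which encodes nucleophosmin, rose by 0.37 (SE 0.09, adjusted p = 0.0359 over all genes), and adjusted over the list alone 3 members rose, the others being FBL at 0.23 (SE 0.08) and DKC1 at 0.19 (SE 0.06). The genes of the G2 and M phases of the cell cycle were higher in 25 of 25 (median 0.17, adjusted p = 5.08e-06). None of them passed over all genes, and adjusted over the list alone 1 rose, the mitotic spindle gene HMMR at 0.38 (SE 0.11). CCNB1 and PLK1 both stood at 0.25 without passing. The cholesterol synthesis genes were positive in 18 of 21 (median 0.12, adjusted p = 0.0371), with PCSK9 at 1.17 (SE 0.36), SQLE at 0.27, HMGCR, the rate-limiting enzyme, at 0.23 and LDLR at 0.20, none past the test over all genes or adjusted over the list alone. The p53 target genes were negative in 17 of 20 (median −0.08, adjusted p = 0.0442), with ZMAT3 at −0.29, TP53I3 at −0.23 and BBC3 at −0.32, none past either test. Leaving out each line in turn kept the first 2 lists past the test in 26 of 26 fits, cholesterol synthesis in 20 and p53 targets in 17. Without the 4 lines whose 2 libraries correlated least (A498, OVCAR-4, SNB-75 and CAKI-1), the G2 and M list did not pass (adjusted p = 0.0778), nor did cholesterol synthesis (0.204) or p53 targets (0.262). Within the flow cells hky73bbxx, H5TJWDMXX and HFCGKDMXX the adjusted p was 2.91e-05, 0.22 and 0.000189 for ribosome biogenesis, 0.000126, 9.46e-05 and 0.00329 for G2 and M, 0.741, 1.92e-08 and 0.815 for cholesterol synthesis, and 0.0354, 0.0400 and 0.866 for p53 targets. None of the 3 lists of ribosome biogenesis, G2 and M, and p53 genes had a member with either 7-base word, and cholesterol synthesis had 1, with ATCGATA.

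The remaining lists did not pass as sets. In the list of G1 and S phase genes, with 12 of 25 positive (adjusted p = 0.798), UHRF1, a cofactor of DNA methylation maintenance, rose by 0.55 (SE 0.11, adjusted p = 0.00255 over all genes), and TYMS, thymidylate synthase, fell by 0.30 (SE 0.09) adjusted over the list alone. Glial and neural genes were negative in 14 of 21 (median −0.31, adjusted p = 0.0915), with NCAM1 at −0.90 and SOX2 at −0.50, which both fell adjusted over the list alone. NCAM1 was also the member that fell in the neuroendocrine list (2 of 8 positive, adjusted p = 0.110), and SOX2 in the pluripotency (5 of 7, 0.870) and dedifferentiated melanoma lists (12 of 17, 0.193). GPNMB, at −0.71, fell adjusted over the melanocytic list alone (12 of 25, 0.343), though of the 5 ME lines that expressed it 3 were higher and 2 lower (mean log2(RPKM + 1) change 0.13), and NOTCH3, at 0.73, rose in the T lymphoid list (7 of 13, 0.758). The unfolded protein and ATF4 list had 18 of 21 positive (adjusted p = 0.110), with HSPA5 at 0.24, past neither test. Housekeeping controls had 14 of 19 positive (0.0601) and basal breast markers 13 of 16 (0.0601). The housekeeping controls passed upward in 8 of 26 fits with a line left out and in 6 of 23 other settings. Basal breast markers did so in 5 and 6, and the unfolded protein and ATF4 list in 3 and 3. Epithelial markers had 17 of 26 positive (0.996) and mesenchymal markers 17 of 27 (0.295), with TGFBI at 0.69 and COL6A3 at 1.02.

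No member of the following lists passed over all genes or adjusted over the list alone, and the camera adjusted p stands beside each count of positive members. These were luminal breast (15 of 21, 0.614), lung epithelial (5 of 13, 0.758), ovarian (11 of 18, 0.481), renal (10 of 17, 0.481), myeloid (13 of 16, 0.215), and erythroid and megakaryocytic markers (7 of 14, 0.870). They were also germline and cancer-testis genes (11 of 16, 0.614), interferon (9 of 29, 0.193), antigen presentation (7 of 19, 0.314), inflammatory NF-kB (13 of 21, 0.798), hypoxia and glycolysis (14 of 20, 0.166), TGF-beta response (12 of 21, 0.481) and immediate early genes (10 of 21, 0.670). The median, mean and test differed in sign in the epithelial, erythroid, G1 and S, immediate early, lung epithelial and pluripotency lists. As medians per line over lines, no list passed, and the lowest p belonged to the lung epithelial list, with a mean of −0.16 over 15 lines (permutation p = 0.00842, adjusted p = 0.227).

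Within panels, the lines of the CNS panel shared a rise of CNN1, which encodes the smooth muscle protein calponin. Its counts went from 30 to 328 in SF-539, from 15 to 316 in SNB-75 and from 1 to 46 in U251, a fitted log2 change of 4.04 (SE 0.64, adjusted p = 0.0236), and the activin receptor gene ACVR2A fell by 1.57 (SE 0.28, adjusted p = 0.0491). In the ME panel, MIGA1 (1.36, adjusted p = 0.0120), the sialomucin gene CD164 (1.21, adjusted p = 0.00829) and the tRNA methyltransferase subunit gene TRMT6 (1.15, adjusted p = 0.0119) rose and were higher in 6 of 6 lines, and ACTR1B fell by 0.59 (adjusted p = 0.0417). In the OV panel, TMEM86A fell by 2.70 (adjusted p = 0.0171), AMOT, the angiomotin gene, by 2.67 (adjusted p = 0.0273), and the RNA polymerase III subunit gene POLR3G rose by 1.84 (adjusted p = 0.0381), each in 3 of 3 lines. SERPINB7 was also called there, but on OVCAR-3 alone, where its count went from 88 to 2037, since IGROV1 and OVCAR-4 had 0 counts in both libraries.

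KDM5B itself passed within BR (log2 change −2.62, SE 0.39, adjusted p = 0.0120), CNS (−2.43, adjusted p = 0.0236), LC (−1.95, adjusted p = 0.00445), ME (−1.47, adjusted p = 0.0275), OV (−3.06, adjusted p = 0.00112) and RE (−2.05, adjusted p = 0.0311), and not within LE. In the RE panel the genes with the largest fitted changes lay near 0 counts in 1 arm. HBE1 went from 0 to 52 counts and MAL from 0 to 42 in CAKI-1, with 0 in both A498 libraries, and HIST1H3B from 0 to 6 in A498 and from 0 to 16 in CAKI-1. STAR, LINC01816 and SNORA27 had 12, 1 and 4 counts in A498 with shLuc and 23, 13 and 9 in CAKI-1, and 0 in all with shKdm5b. The fitted folds of these 6 genes depend on the prior count and are not given.

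The edgeR fit called 0 genes up and 1 down in BR, 1 and 2 in CNS, 0 and 1 in LC, 8 and 2 in ME, 2 and 7 in OV, and 221 and 150 in RE. In LE it called 0 genes, with 720 at an unadjusted p under 0.05, 2 by limma and 34 by DESeq2. These calls rested on few lines. Without CAKI-1 or A498 the RE calls were 4302 or 1282, on 1 line each with the spread taken from the other panels, and the CNS calls were 20, 0 and 1 without SF-539, SNB-75 and U251. The BR count was 2, 0 and 0 without BT-549, MCF7 and T-47D, the LC count 6 without EKVX, and the LE count 15 without CCRF-CEM. In ME it was 0 without MALME-3M or UACC-257, 2 without SK-MEL-28 or SK-MEL-5, 5 without LOX_IMVI and 28 without UACC-62, and in OV 19, 52 and 14 without IGROV1, OVCAR-3 and OVCAR-4. Without the pairing of libraries by line edgeR made 0 calls over all panels (453 at an unadjusted p under 0.05), against 395 with it, in which a gene called in several panels, as KDM5B was in 6, counts in each.

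Whether a gene's change differed between panels was tested directly. The smallest p belonged to SOX6, a transcription factor gene with log2 changes of 2.45 in BR and −2.64 in OV, and it did not pass (adjusted p = 0.0688). The next were PRUNE2 (5.26 in RE), LTB4R, a leukotriene receptor gene (−1.29 in RE), MIR5703 (2.97 in RE), ZNF649 (−2.44 in RE, −1.12 in OV) and IRAIN (2.89 in RE), each with an adjusted p of 0.187. The edgeR F test called 0 genes, with 1510 at an unadjusted p under 0.05, while limma called 24 and DESeq2 459. Without CAKI-1 the RE panel was A498 alone, so the edgeR test then set a single line against the other panels.

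The title of the series names cell identity, so markers of each line's own lineage were followed. In the ME line MALME-3M the pigment genes DCT and TYRP1 went from 18.9 to 217 and from 2.23 to 18.6 RPKM, and in SK-MEL-28 TYRP1 went from 3.71 to 22.4. In UACC-62 PMEL went from 8.09 to 1.09 RPKM and DCT from 13.3 to 3.28. GFAP, the astrocyte filament gene, went from 7.27 to 45.6 RPKM in SNB-75 and from 109 to 28.9 in U251. The embryonic globin gene HBE1 went from 2994 to 760 RPKM in K-562 and the granule protease gene PRTN3 from 4402 to 1739 in HL-60, while the recombinase gene RAG1 went from 30.4 to 75.4 in CCRF-CEM. NKX2-1, a lung lineage transcription factor gene, went from 8.48 to 1.49 RPKM in NCI-H322M and from 116 to 65.9 in HOP-92. It went from 2.06 to 2.57 in NCI-H522, and of the 4 LC lines that expressed it 2 were higher and 2 lower. In the breast lines, AGR2 went from 2.57 to 6.72 in MCF7 and from 70.7 to 127 in T-47D, and COL6A2 from 9.72 to 23.8 in BT-549, for which the mesenchymal list was followed in place of a breast list. KLK8 went from 28.8 to 6.29 in OVCAR-3 and SPON1 from 21.4 to 67.0 in OVCAR-4, and the cadherin gene CDH6 from 1.91 to 33.7 in A498 and from 37.7 to 11.8 in CAKI-1. Each of these is a single pair of libraries with no replicate check.

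Over all lines the own-lineage markers showed no shared direction. The median log2 change of each line's own list ran from −0.91 in K-562 to 0.77 in MALME-3M and was positive in 10 lines and negative in 16. Its mean over lines was −0.09 ± 0.37 (SD, n = 26, two-sided sign-flip permutation p = 0.232). In the ME panel it was positive in 5 of 6 lines (mean 0.17 ± 0.42, exact sign-flip p = 0.375) and in the LC panel negative in 5 of 6 (mean −0.14 ± 0.14, exact sign-flip p = 0.0938). The medians rested on 9 (LOX_IMVI) to 25 (MALME-3M) expressed markers per line in ME, but on only 5 (NCI-H226) to 9 (EKVX) in LC. With 6 lines the exact two-sided test can reach a p under 0.05, and with 3 lines or 2 it cannot, so the other panels have means only: 0.14 in BR (0.36 in BT-549 on the mesenchymal list, −0.06 in MCF7 and 0.11 in T-47D), −0.34 in CNS, −0.34 in LE, −0.06 in OV and −0.35 in RE. Within hky73bbxx the mean was −0.10 (p = 0.258), within H5TJWDMXX −0.09 (exact p = 0.688) and within HFCGKDMXX −0.02 (exact p = 1).

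**Figure D4:**
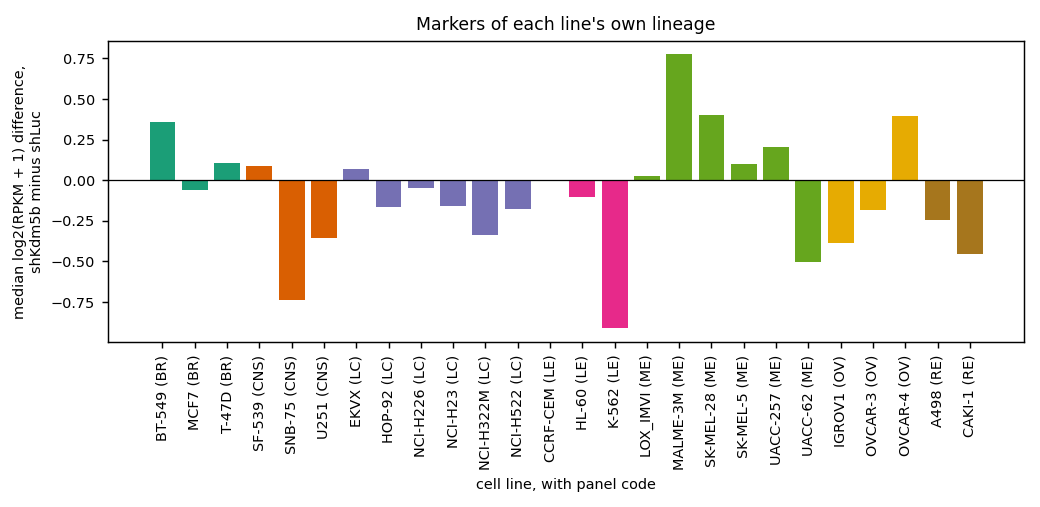
Median log2(RPKM + 1) change, shKdm5b minus shLuc, over the expressed markers of each line's own lineage, 1 bar per line, coloured by panel. The bars run from −0.91 in K-562 to 0.77 in MALME-3M, with 10 above 0 and 16 below. They rest on unequal numbers of markers, from 5 (as in SF-539 and NCI-H226) to 25 (as in MALME-3M).

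The 100 genes most enriched in each line moved both ways as well. Their mean log2 change ran from −0.44 in MALME-3M to 0.35 in OVCAR-3, and its mean over 26 lines was 0.00 ± 0.18 (SD), positive in 16 lines (two-sided sign-flip permutation p = 0.998). The lines were slightly more alike in expression with shKdm5b, at a mean correlation between lines of 0.753, against 0.744 with shLuc, a difference of 0.00872 (permutation p = 0.0495 from 10000 swaps within lines). That call was lost with rank correlations (difference 0.00701, p = 0.108), with a pseudocount of 0.1 (p = 0.0525), without the 4 least correlated lines (difference 0.00374, p = 0.244) and in 18 of 26 fits with a line left out. Within flow cells the difference was 0.0141 in hky73bbxx (permutation p = 0.0185), 0.00634 in H5TJWDMXX (permutation p = 0.689) and 0.00536 in HFCGKDMXX (permutation p = 1), each from random swaps. Between lines of the same panel the correlations were 0.807 and 0.802 (difference 0.00491, permutation p = 0.309).

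The number of genes with an absolute log2(RPKM + 1) change of 1 or more ran from 90 in the ME line LOX_IMVI to 3422 in the RE line A498, with a median of 361. By panel it averaged 302 ± 196 in BR (SD, n = 3), 591 ± 493 in CNS (n = 3), 270 ± 170 in LC (n = 6), 317 ± 225.7 in LE (n = 3), 418 ± 243 in ME (n = 6), 1105 ± 868 in OV (n = 3) and 2586 ± 1182 in RE (n = 2). The number showed no relation to the size of the KDM5B change (r = −0.0743, permutation p = 0.734, and rho = −0.259, p = 0.201) or to the KDM5B level with shLuc (r = −0.131, permutation p = 0.526, and rho = 0.0787, p = 0.701) that passed a test. The adjusted p was 0.734 for each, over both coefficients of the 2 relations together. Without NCI-H522 and OVCAR-3, farthest from the median KDM5B change, r was −0.0633, and without NCI-H522 and A498, farthest in KDM5B level, 0.196. Within hky73bbxx (17 lines) r was 0.0210 (p = 0.945) and −0.166 (p = 0.518), and the other flow cells held too few lines.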

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

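Of the tests in this part, the removal of trends in the RE panel and the permutations without single lines or panels were chosen after the result was seen, while the swap of the CAKI-1 libraries was set before its result was seen.

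Among the 6 LC lines, the median log2 change of ribosome biogenesis genes in NCI-H522 was 0.51 and stood apart from the next highest, 0.11. The median of G2 and M phase genes in EKVX was −0.37, with the next lowest line at 0.10. The median of p53 target genes in HOP-92 was −0.28, with the next lowest at −0.09. In all, 16 groups of 6 lines were examined this way, 3 stood out, and chance sets apart about 1 in 20 such groups.

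The number of genes with an absolute log2(RPKM + 1) change of 1 or more differed between panels (permutation p = 0.00422, adjusted p = 0.0338 over 8 measures), with means of 2586 in RE (n = 2), 1105 in OV (n = 3) and 270 in LC (n = 6). Without the RE lines the permutation p was 0.0745. Without A498, without CAKI-1 and within flow cell hky73bbxx the RE panel was a single line, so the p-values of those permutations are not given. The size of the KDM5B change did not differ between panels after adjustment (permutation p = 0.0495, adjusted p = 0.198).

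The RE panel held 371 of the 395 calls made in single panels, on 2 lines. A trend of the log2 changes with transcript length, GC share and expression was present in A498 (rank correlations over genes, which are not independent replicates, of 0.486, −0.503 and −0.266) and ran the other way in CAKI-1 (−0.173, 0.229 and 0.180), but of 691 RE calls by limma 250 were also made in the same direction after removing it within lines (328 calls in all), which argues against it as the whole source. With the CAKI-1 libraries exchanged, the same fit called 3888 genes, more than the real 371. The changes of both lines correlated at −0.241 across genes, and the exchange turned that sign. It therefore cannot tell a spread in these lines larger than the pooled one from their opposite trends. The log2 changes had SDs of 1.17 in A498 and 1.001 in CAKI-1 against a median of 0.645 in the other 24 lines. Whether a response of renal lines adds to the calls stays open and untested, since the panel had 1 library per arm in each of 2 lines.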

How the results depend on the processing

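The alternatives without the 4 lines whose libraries correlated least (A498, OVCAR-4, SNB-75 and CAKI-1), without word genes, adjusted for gene properties, on differences in log2 CPM and with edgeR's newer fit were added after seeing the data. The cause of each difference was not tested, except that single flow cells, panels or lines left out hold fewer samples. The panel fit within H5TJWDMXX could not be made, with 1 line per panel, and no unpaired test of differences between panels was made.

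The count of 281 genes over all lines became 5 without the pairing by line, which left KDM5B at −2.14, and 615 with DESeq2. It became 523 without the 4 least correlated lines. Within hky73bbxx, H5TJWDMXX and HFCGKDMXX it was 109, 0 and 0 (edgeR, 731 and 728 at an unadjusted p under 0.05 in the latter 2). Without LC, ME and RE it was 103, 124 and 5.0e+02 (315 higher, 183 lower). Without word genes it was 61, with the p-values adjusted again over the rest. Adjusted for length, GC and expression it was 542 (limma on log2 CPM differences of 16302 genes, where it was 312 unadjusted). The count over all lines stayed within 1.5 times in 14 others. Against 198 higher and 83 lower by edgeR, the balance was about even with limma on log2(RPKM + 1) (135 and 128), which changed both tool and scale. Against that limma fit, a pseudocount of 0.1 left it about even (142 and 134), and array weights gave 179 and 238. With each line left out the edgeR count ran from 183 (without U251) to 506 (without A498). The KDM5B change lost its call within H5TJWDMXX (−2.29, adjusted p = 0.454) and HFCGKDMXX (−1.88, adjusted p = 0.675), kept it in 23 other settings, and ran from −2.10 to −1.99 with each line left out.

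The 4 lists became 7 with no filter, 2 with DESeq2, with array weights and without OV (ribosome biogenesis and G2 and M), 2 without the 4 lines (ribosome biogenesis and, at an adjusted p of 0.00178, unfolded protein and ATF4, with G2 and M lost at 0.0778), 9 within HFCGKDMXX, and 0 with an estimated correlation (camera, 2 at an unadjusted p under 0.05), and 2 (without T-47D, MALME-3M or IGROV1) to 6 with each line left out. The 395 panel calls by edgeR (232 higher, 163 lower) became 0 without the pairing by line (edgeR, 453 at an unadjusted p under 0.05). They became 2.3e+02 (148 higher, 78 lower) with no filter, 3970 within hky73bbxx, 0 within HFCGKDMXX (1096 unadjusted) and 95 without the 4 lines. DESeq2 made 1710. Limma on log2(RPKM + 1), which changed both tool and scale, made 971. Against those 971, limma made 1075 with median-centred values (444 higher, 631 lower) and 815 with a pseudocount of 0.1. On differences in log2 CPM limma made 774. With each line left out the edgeR calls ran from 262 (without NCI-H226) to 4379 (without CAKI-1), with 648 without OVCAR-4 and 1364 without A498. The 0 genes differing between panels (edgeR, 1510 unadjusted) became 1 with no filter and without the 4 lines, 879 within hky73bbxx and 459 with DESeq2. Limma on log2(RPKM + 1) called 24. That limma count fell to 16 with median-centred values and to 7 with a pseudocount of 0.1. With each line left out edgeR called 0 to 1816 (without CAKI-1).

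The mean change of line-enriched genes, near 0, turned negative with 50 genes (−0.00792), within hky73bbxx (−0.00356) and within HFCGKDMXX (−0.103), and ran from −0.0141 to 0.0176 with each line left out. The difference in similarity lost its call with a pseudocount of 0.1 (0.00693, permutation p = 0.0525) and with Spearman correlations (0.00701, p = 0.108). It also lost it without the 4 lines (0.00374, p = 0.244) and in 18 of 26 fits with a line left out (0.00595 to 0.0103). H5TJWDMXX (0.00634) and HFCGKDMXX (0.00536) hold 5 and 3 lines, too few for swaps to give a p under 0.05. The median of 361 changed genes per line became 1220 with a pseudocount of 0.1 and 23 at an absolute log2 change of 2, and 331 to 391 with each line left out. Own-lineage markers (−0.123 to −0.0553) and similarity within panels (0.00250 to 0.00806) stayed short of their thresholds with each line left out. The 23 other named genes gave 1150 gene and setting pairs: 1051 kept direction and call, 99 lost the call (23 each within H5TJWDMXX and HFCGKDMXX, 20 without the pairing, 7 within hky73bbxx, 6 without LC), and 0 turned. Limma on log2(RPKM + 1) ended the calls of ALDH1A2, PDGFRB, ADAM12 and GUCY1B3. Depth limits the RE genes near 0 counts.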

Other observations

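The word tests, their predictions from the hairpins and from base composition, the choice and tally of the genes in the next paragraph, and the panel counts without KDM5B were made after the results were seen, while the exchanges of libraries and panel codes were planned.

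Of 40 lineage markers expressed in at least 3 lines of the ME, LC, CNS or OV panel, 9 moved 1 way in all of these lines, where even odds in each line would give 4.53, and no test was made. The 9 were 2 of 24 in ME, 2 of 6 in LC, 3 of 4 in CNS and 2 of 6 in OV, and are given as log2(RPKM + 1) changes. In the ME panel TYRP1 was higher in 4 of 4 lines (mean 1.60 ± 1.03 SD) and the transcription factor gene SOX10 lower in 5 of 5 (−0.37 ± 0.30), while DCT was higher in 1 line and lower in 4 (0.13 ± 1.96). In the CNS panel the stem cell factor gene SOX2 was lower in 3 of 3 lines (−0.87 ± 0.48), the glutamate transporter gene SLC1A3 higher in 3 of 3 (0.89 ± 1.08) and the neuronal tubulin gene TUBB3 higher in 3 of 3 (0.62 ± 0.52). In the LC panel the alveolar genes AGER (−0.26 ± 0.15) and ABCA3 (−0.28 ± 0.16) were lower in 5 of 5 lines. The folate receptor gene FOLR1 was lower in 3 of 3 OV lines (−0.49 ± 0.28) and SPON1 higher in 3 of 3 (0.60 ± 0.87).

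A hypothesis for the rises is that 1 of the hairpins acts on transcripts that hold GTACCAA, as a small RNA does through its first bases. The word chosen on 13 lines was again the first of all words in the other 13 (t = 21.9). All lines carried hairpins of the same labels and lost KDM5B, so this repeat cannot tell a hairpin from another cause shared by the lines. The median log2 change was 0.14 with the 8-base match, 0.09 and 0.02 with the 7-base forms and −0.01 with 6 bases, against 0.00 with none. These medians came from the genes and lines on which the word was chosen, so they are not separate evidence. Base composition was an unlikely source, since the largest t of the other 419 words of the same bases was 10.03 against 28.1. Loss of KDM5B acting in proportion to the knockdown cannot be told apart from no relation, since r of the effect with the KDM5B change was 0.193, while the unadjusted version gave r = 0.537 (permutation p = 0.0037), with a larger effect where KDM5B fell less. The hairpin sequences were not analysed here, so repression by the control hairpin, with these genes lower in shLuc, may be the source but is not established.

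A second hypothesis is that the shKdm5b hairpin itself acts on other transcripts that hold ATCGATA. KDM5B holds 1 site of this word, in its coding sequence, which the hypothesis needs (7.94% of 970 genes of similar length hold the word). The most negative t of other words of the same bases was −6.62 against −10.3, which argues against base composition, and the word ranked first for falls in both sets of 13 lines (t = −8.07 and −7.91). As for GTACCAA, that repeat cannot tell a hairpin from another cause shared by the lines. ATCGATA did not pass the flips of whole lines over all words (permutation p = 0.325, and 0.269 with lines unscaled). Each flip was scored by its strongest word, which reached as far as t = 22.03 and −22.81. A weaker word thus has little power in this test, which cannot decide whether the pattern is chance among words. Taken alone, the word's effect over lines gave a sign-flip p of 1e-05, but the word was chosen on these lines.

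In the first version of the word tests, without the GC share and with differences of means, GTACCAA had t = 28.4 and a flip p of 0.0170 over all words, and was higher in 21 of 26 lines (mean 0.14 ± 0.17 SD). ATCGATA had t = −9.98, a flip p of 0.723 over all words, and was lower in 24 of 26 lines (mean −0.12 ± 0.21), with r = 0.606 (permutation p = 8e-05) to the KDM5B change. Both words ranked first in all lines and in both sets of 13 lines.

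Exchanging the 2 libraries within random sets of lines, with edgeR's newer fit, gave a result as large in 1 of 100 splits, the real one, with 365 genes against at most 2 in the others, so chance can be excluded for the count over all lines. For the panels, with limma on log2(RPKM + 1), 1 of 32 splits was as large in ME (50 genes, highest other 23, and 49 genes without KDM5B), the smallest share possible, so chance can be excluded there only without adjustment over the 6 panels. In LC 1 of 32 was as large (1 gene, highest other 0), but the gene was KDM5B, the target of the hairpin, and with it set aside the count was 0, so this split says nothing beyond the knockdown. The 4 splits of BR (real 2, highest other 0, 1 as large), CNS (46, highest other 31, 1 as large), LE (2, highest other 28, 3 as large) and OV (140, highest other 154, 2 as large) are too few for a share under 0.05. With panel codes permuted over lines, 4 of 100 arrangements, the real one among them, gave at least the real 24 genes differing between panels. That is under the bound of 5 set before, but by limma only and without adjustment over the other exchange tests. The edgeR F test called 0 genes (smallest adjusted p = 0.0688), so chance is not excluded for this count. The highest other gave 239, several times the real count, which points to a structure of the samples whose source was not tested.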
